A study of Arabis alpina with 9 samples.

How the data were processed

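The deposited count table held integer read counts per gene for the 9 mutant libraries, as deposited by the authors, with 34220 gene entries and 5 special entries for reads without a gene. Per the submitters' processing notes, the tools named are STAR, HTSeq 0.5.4p1, DESeq and DESeq2. The notes give no role or order for them, and the genome build and annotation are not given in the sources used here. Per the labels, polyadenylated RNA was isolated with RNeasy kits, libraries were made with a NEBNext directional kit, and single reads of 100 bases came from a HiSeq2500. The time of day of harvest is not given in the sources used here.

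The authors also deposited 6 gene lists, of genes higher or lower in the mutant than in its control at the 3-week apex, the 5-week apex and the 5-week leaf. Per the file headers, each list gives a fold change, the ratio of the mutant mean to the control mean, as made by the authors. The log2 fold change in these lists is the binary logarithm of that ratio, as deposited by the authors. The adjusted p-value (p adjusted for many tests) was also made by the authors, and no list entry exceeds 0.05 or is under 2-fold. The mean expression signal of the lists is a mean of normalized counts, as deposited by the authors. The mutant mean was printed as the authors' value, and the mean over both groups only ordered ties of fold. The 6 columns of control means were not used here, because they belong to no sample of this series, and control libraries were not analysed here. In 10 entries the mutant mean was blank and was taken as 0, because the authors' log2 fold change there was minus infinity.

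In each list the authors' mutant mean was a constant times the mean of the 3 deposited libraries of that group, with median ratios of 0.981, 0.891 and 1.00. All listed genes with a mean count of at least 10 lay within 5% of that constant, against 1.37% to 6.69% for groups other than the list's own. The lists and the libraries therefore describe the same mutant samples, and changes of listed genes between these libraries are not independent evidence.

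Gene names came from the lists, which hold 1487 gene IDs, 1079 of them (72.6%) paired with an Arabidopsis gene. No other source of names was used here. Of the 30538 counted IDs 1068 had more than 1 entry, and 8 such IDs of the lists were left out of gene naming. Of 447 genes in the 23 lists fixed beforehand, 68 were paired with an ID and 65 had values in the tested genes. LFY, AP1, SOC1, FLC and SVP were not analysed here.

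Counts of the 9 libraries were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, its expression filter and the quasi-likelihood F-test in 1 model with 3 groups. Benjamini-Hochberg adjustment was applied over the 20633 genes kept, at an adjusted p of 0.05. The SE printed with a log2 fold change was derived from that test, as the absolute log2 fold change over the square root of F. The common biological coefficient of variation was 0.0768 and the prior degrees of freedom were 9.80. CPM are counts per unit of TMM-scaled library size. A prior of 3 counts was used only for logarithms in ordinations, correlations and the tests of gene lists. For a group without counts a bound against 3 counts was given in place of the fitted fold, and for 1 to 3 counts the ratio with a 95% counting interval. DESeq2 1.42.0 and limma 3.58.1 with voom served as other tools. Tables and exact tests used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.

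Known changes were put into simulated counts, drawn from the mean of the baseline group and the fitted spread of each gene. Folds of 1.5, 2 and 4 went into 67, 67 and 66 genes, far fewer than the real contrasts called. Recovery and false calls under changes as wide as the real ones, which also bear on scaling, were therefore not tested. For folds of 1.5, 2 and 4 put into genes, 67.2%, 95.5% and 95.5% were recovered between the apex ages, with 9 false calls among 181. Between leaf and apex 58.2%, 80.6% and 97.0% were recovered, with 13 false calls among 170.

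Gene lists with at least 3 tested members were tested with camera of limma, with a preset correlation of 0.01 and with an estimated correlation, and with the rotation test fry. Camera sets the members of a list against all other genes, whereas fry asks only whether the members changed. These were the lists for auxin, the clock, cytokinin, gibberellin, glucosinolate, jasmonate and salicylic acid. Members of the other fixed lists appear only as single genes. The authors' lists were tested in the contrast that shares no library with them. Overlaps of the lists used Fisher's exact test against 22769 genes, those with at least 10 counts over the libraries or listed.

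Named genes followed a fixed rule. Per contrast it took the 10 genes with the largest fold in each direction that have an Arabidopsis name, pass the adjusted p, have an average log2 CPM of at least 2 and show no overlap between the groups. That average runs over all 9 libraries, the leaf included. The rule added up to 2 genes without a name per direction, the 3 members of each fixed list with the smallest adjusted p, and key flowering genes. Per authors' list it took the 10 named genes with the largest fold and every member of the fixed lists. Genes outside the rule are named only where the text says that they were chosen after their values were seen.

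The grouping, the contrasts, the gene lists, the naming rule, the thresholds and most alternative settings were chosen before the data were examined. The phase test of clock genes, the direction test within the authors' lists, leave-one-out runs of the list tests, mutant means of listed genes and bounds without each library, the count of genes lowest in each library and RLE scaling for the authors' lists were chosen after the data were seen. Replicate numbers did not pair libraries across groups, with correlations of same-number residuals between -0.143 and 0.00514.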

Results

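Arabis alpina is a perennial relative of Arabidopsis thaliana, and the series concerns how AaTFL1, its counterpart of the floral repressor gene TFL1, takes part in the control of flowering. Polyadenylated RNA was sequenced from the eop089 mutant of the accession Pajares, grown in long days. The labels give this mutant by its line name only. Dissected shoot apices were taken at 3 and at 5 weeks of age and leaves at 5 weeks, with 3 libraries each, so that 9 mutant libraries were measured. Each library held between 11859813 and 13382460 counts in genes. Between 22212 and 23176 genes had at least 1 count.

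Libraries of the same group were alike, with correlations across genes of log2 CPM between 0.985 and 0.993 (genes are not independent replicates). No pair agreed within counting noise, the chi-square of their counts per degree of freedom lying between 1.68 and 11.1, so every library was counted as a replicate. The first principal component held 91.6% of the variance and set the leaf apart from both apex groups, and the second, with 5.35%, parted the apex ages. The 10 most abundant genes took 12.5% ± 0.228 (SD, n = 3) of the leaf counts, 3.14% ± 0.0321 (SD, n = 3) at the 3-week apex and 2.94% ± 0.0748 (SD, n = 3) at the 5-week apex. Nothing in the labels says that replicates came from separate plants or pools, so p-values measure only the spread between these samples, which may be technical.

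At the 3-week apex the 2 listed floral repressor genes and the listed evening clock genes were higher in the mutant than in its control, as were DRM2 and BRC1. In the authors' deposited table TFL1 (Aa_G789610) had a fold of 2.12 in the mutant over the control, with a mean of 457.66 normalized counts in the mutant and an adjusted p of 2.98e-11. TEM1 (Aa_G596330), a repressor of the florigen gene FT, had a fold of 2.28 in the authors' deposited table, with an adjusted p of 1.18e-14. The dormancy-associated gene DRM2 (Aa_G438760) had a fold of 10.72 and a mutant mean of 2883.73 in the authors' deposited table. BRC1, which holds back the outgrowth of axillary buds, had a fold of 3.57 in the authors' deposited table. The evening clock genes BOA, ELF4, FKF1 and LUX had folds of 3.73, 3.62, 3.13 and 2.08 in the authors' deposited table.

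Defence and hormone genes were also listed at the 3-week apex. LOX2 and AOC2, which act in jasmonate synthesis, had folds of 5.86 and 3.79 in the authors' deposited table, and the dark-inducible gene SEN1 one of 6.08. All 3 listed genes of the glucosinolate list were higher in the authors' deposited table, with folds of 7.32 for BCAT4, 2.95 for CYP79F1 and 2.05 for MYB29. The mutant means of BCAT4, CYP79F1 and AOC2 rested largely on 3-week apex replicate 1, without which they moved from 1.31 to 0.370, from 3.38 to 1.38 and from 1.32 to 0.871 CPM. The photosynthesis gene CA1 was also listed higher, and without the same replicate its mean moved from 16.9 to 9.23 CPM. The auxin-responsive genes IAA29 and IAA1 had folds of 3.61 and 2.08, while the auxin synthesis gene YUC6 stood at 0.454 of the control in the authors' deposited table. Both listed flavonoid genes were lower, TT7 at 0.449 and FLS1 at 0.477 of the control in the authors' deposited table. Genes lower by more were ATSDI1 (0.148) and LSU2 (0.267), both named for their response to low sulphur, TEL1 (0.189), ERF6 (0.217) and GPT2 (0.268), per the authors' deposited table. AT5G28885 (Aa_G795460) was lower, listed at 0 in the mutant in the authors' deposited table. In all, 242 genes were higher and 85 lower in the authors' deposited table for this setting, with median log2 fold changes of 1.41 and -1.35 over genes with a finite fold.

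At the 5-week apex fewer genes were listed, and evening clock genes were again higher in the mutant. JMJD5 (Aa_G133240), a clock-associated histone demethylase gene, had a fold of 9.08 and a mutant mean of 242.06 in the authors' deposited table. COR27, a cold- and clock-regulated gene, had a fold of 37.86 and a mutant mean of only 25.93 in the authors' deposited table. Replicate 1 was the highest for both. Without it the mean of JMJD5 moved from 17.8 to 9.28 CPM and that of COR27 from 1.91 to 1.12. Replicate 2 was the lowest for both, at 6.07 CPM for JMJD5 and 0.334 for COR27, against 12.5 and 1.92 in replicate 3. ELF4, FKF1, BOA and LUX were higher again, with folds of 6.65, 4.93, 2.88 and 2.17 in the authors' deposited table. For all 4 of these genes replicate 2 was the lowest 5-week apex library, with a median of 0.533 of the mean of the others. It was the lowest for 44 of 61 genes listed higher at this age with counts in each library, and replicate 1 for 24 of 40 listed lower. The morning clock gene PRR9 was lower, at 0.484 of the control, and so was the light-harvesting gene LHCB2.1, at 0.492, in the authors' deposited table.

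DRM2 was higher at this age too, with a fold of 8.53 in the authors' deposited table. The tryptophan-derived glucosinolate genes CYP79B3 and CYP79B2 had folds of 8.09 and 2.29, and the phloem sucrose transporter gene SUC2 one of 2.22, in the authors' deposited table. The galactinol synthase gene GolS1 stood at 0.16 of the control, STH at 0.308, TEL1 at 0.353 and WRKY25 at 0.379 in the authors' deposited table. The CYP79B3 level came from 5-week apex replicate 3, at 2.51 CPM against 0.322 and 0.334 in replicates 1 and 2, and that of GolS1 moved from 0.419 to 0.0667 CPM without replicate 3. AT5G28885 stood at 0.0186 of the control in the authors' deposited table. TFL1 and TEM1 were not among the 66 higher and 50 lower genes of the authors' deposited table at this age, and whether their change differed between the ages was not tested.

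The leaf held the longest lists, and its listed genes of salicylic acid, defence and jasmonate were all lower in the mutant. All 8 listed genes of the salicylic acid and defence list were lower in the authors' deposited table. Among them were the defence marker PR1, at 0.0532 of the control, WRKY53 at 0.11, WRKY46 at 0.142, SARD1 at 0.178 and EDS5 at 0.199 in the authors' deposited table. The 4 listed jasmonate genes were also lower, with JAZ1 at 0.266, AOS at 0.289, LOX3 at 0.337 and AOC2 at 0.5 of the control in the authors' deposited table. Leaf replicate 3 was the lowest of the 3 leaf libraries for all 7 measured genes of the former list, all 4 jasmonate genes and 4 of the 5 listed glucosinolate genes, with medians of 0.745, 0.490 and 0.703 of the mean of the other replicates. Over all genes listed lower in the leaf that had counts in each leaf library it was the lowest for 450 of 618, although leaving it out moved no mean of these defence, jasmonate or glucosinolate genes by more than 1.5 times. Both listed genes of the heat shock and touch list, markers of handling, were lower as well, TCH4 at 0.327 and HSP90.1 at 0.392 of the control in the authors' deposited table, so a difference in handling is not excluded. The florigen gene FT (Aa_G437270) stood at 0.389 of the control (adjusted p of 6.41e-04), and SPL4, a promoter of flowering, at 0.401, in the authors' deposited table. BFT, a relative of TFL1, was at 0.1 of the control in the authors' deposited table.

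The listed gibberellin, cytokinin and auxin genes, few of each fixed list, were higher in the mutant leaf. GA20OX2, a gibberellin synthesis gene, had a fold of 11.73, and RGL3 and RGL2, which encode DELLA proteins, had folds of 2.96 and 2.1 in the authors' deposited table. The cytokinin oxidase genes CKX3 and CKX5 had folds of 8.77 and 2.8, and the response regulator gene ARR15 one of 2.89, in the authors' deposited table. The 4 listed auxin genes GH3.1, IAA29, TAA1 and IAA19 had folds of 3.41, 3.31, 2.32 and 2.1 in the authors' deposited table. PDF1, an epidermal gene, had a fold of 54.37 and a mutant mean of 142.48 in the authors' deposited table, but 1 mutant leaf library carried most of that mean. Its normalised level was 39.2 CPM in leaf replicate 3 against 4.64 and 2.87 in replicates 1 and 2. The stomatal lineage marker TMM, the cyclin gene CYCB1;3 and the xylem markers LAC4 and LAC17 were listed higher too, and the guard cell marker KAT1 lower. The mean of TMM moved from 3.64 to 2.34 CPM without leaf replicate 3. The 5 listed glucosinolate genes were lower, from 0.183 of the control for SOT16 to 0.38 for CYP79B2 in the authors' deposited table. In the clock, TOC1 and PRR5 were higher, with folds of 2.22 and 2.3, and LHY and CCA1 lower, at 0.313 and 0.48 of the control, in the authors' deposited table. Set against the other named genes of the leaf lists, no fixed list leaned to 1 direction past the threshold. The smallest value was an adjusted p = 0.0911, for the auxin and for the salicylic acid list (Fisher's exact test, two-sided, Benjamini-Hochberg over 7 lists, chosen after the values were seen). The leaf lists held 397 higher and 801 lower genes, with median log2 fold changes of 1.43 and -1.66 in the authors' deposited table over genes with a finite fold.

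**Figure D1:**
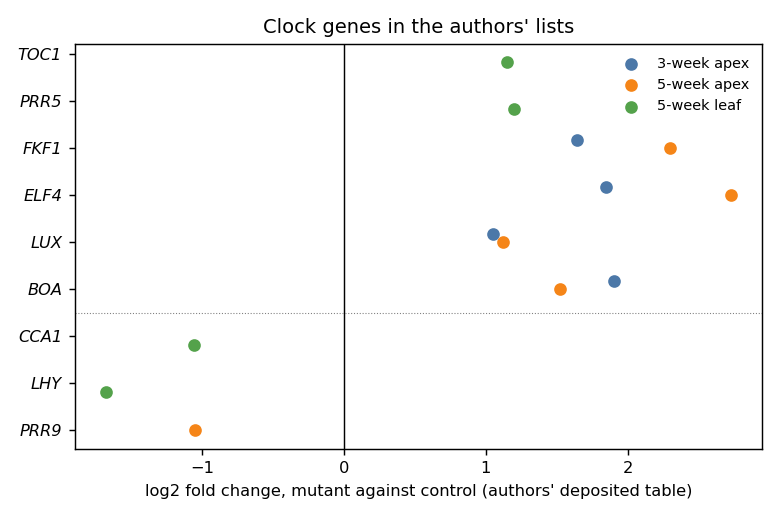
Log2 fold change of the mutant against the control for each listed clock gene, from the authors' deposited table, with 1 point per gene and setting and evening genes above the dotted line. All 6 evening genes lie above 0 and all 3 morning genes below 0 in each setting where they were listed.

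Evening and morning genes of the clock list went opposite ways in the mutant. Of the 9 listed clock genes, out of 24 in the clock list, the 6 evening genes (TOC1, PRR5, FKF1, ELF4, LUX and BOA) were higher wherever the authors' deposited table listed them. The 3 morning genes (CCA1, LHY and PRR9) were lower wherever listed. Directions were pooled over the settings, with 4 evening and 0 morning genes listed at the 3-week apex, 4 and 1 at the 5-week apex and 2 and 2 in the leaf. A two-sided exact permutation of the phase labels gave p = 0.0119, the smallest its 84 arrangements allow, and an adjusted p = 0.0179 by Benjamini-Hochberg over the 3 phase tests run. From the 5-week apex to the mutant leaf all 6 evening genes fell and all 3 morning genes rose, with an evening minus morning log2 change of -4.70 (exact permutation, two-sided, p = 0.0119). From the 3-week to the 5-week apex that value was -1.34 (exact permutation, p = 0.0476), but among the morning genes only PRR9 rose, and CCA1 and LHY did not pass (edgeR adjusted p = 0.887 and 0.465). These permutations run over genes and ignore the spread between libraries. Single replicates of the 5-week apex deviated from the mean of the others by values of like size (1.45 and -1.34). A single library varies more than a group mean, so whether the value between the ages exceeds the spread of group means was not tested. The phases were assigned from textbook knowledge and the test was chosen after the values were seen. No harvest time is known for any group, so the clock values between groups cannot tell age or organ from time of day.

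The lists of the 3 settings shared genes in the same direction. The 3-week and 5-week apex shared 37 higher genes, where 0.701 would be expected by chance (Fisher's exact test, two-sided, Benjamini-Hochberg over 12 pairs, adjusted p = 2.24e-55). They also shared 23 lower genes, against 0.187 expected (adjusted p = 3.30e-43, same exact test). The 3-week apex and the leaf shared 39 higher genes against 4.22 expected (exact test, adjusted p = 1.20e-25) and 29 lower genes against 2.99 (adjusted p = 8.80e-21). The 5-week apex and the leaf shared 17 higher genes against 1.15 expected (exact test, adjusted p = 2.51e-15) and 13 lower genes against 1.76 (adjusted p = 2.44e-08). Of the 6 pairs of opposite direction, 1 passed, with 7 genes higher at the 5-week apex and lower in the leaf against 2.32 expected (exact test, adjusted p = 0.0143). These 7 included CYP79B2, CYP79B3, WRKY40 and XTH18, and with the authors' adjusted p held under 0.01 the overlap was 3 genes with an adjusted p = 0.277. No gene changed direction between the 2 apex ages, and the other opposite pairs gave adjusted p-values from 0.278 to 1.

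**Figure D2:**
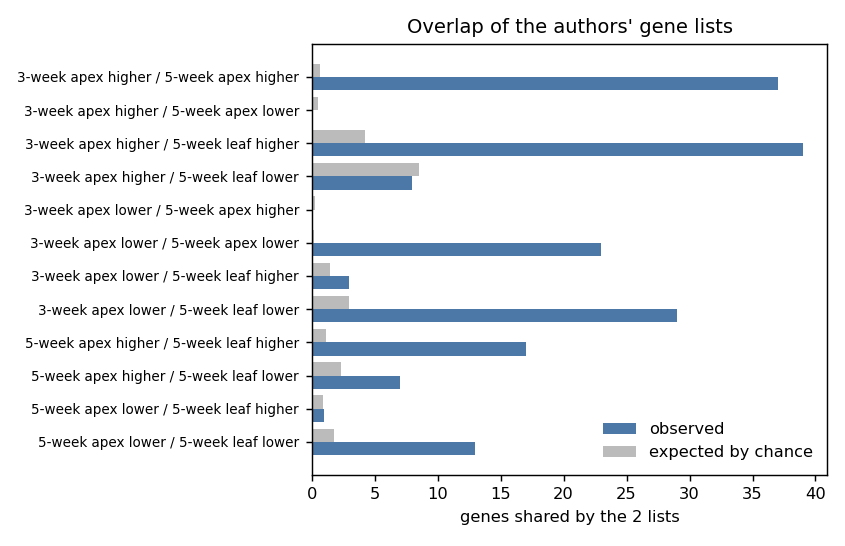
Number of genes shared by each pair of the authors' 6 lists (blue) beside the number expected by chance (grey), in genes. Pairs of the same direction share 13 to 39 genes, and pairs of opposite direction at most 8.

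Altogether 23 genes were listed in all 3 settings, 12 of them higher and 9 lower throughout. DRM2 had folds of 10.72, 8.53 and 10.79 at the 3-week apex, the 5-week apex and the leaf in the authors' deposited table. The asparagine synthase gene ASN1 had folds of 4.79, 2.27 and 4.65, and PKS4 folds of 3.11, 4.14 and 4.04, in the authors' deposited table. The leaf mean of ASN1 moved from 77.3 to 44.1 CPM without leaf replicate 3. The ubiquitin-conjugating enzyme gene UBC28 stood at 0.391, 0.468 and 0.294 of the control in the authors' deposited table. The remaining 2, WRKY40 and AT2G43590, were higher at both apex ages and lower in the leaf. ASN1, PKS4, UBC28, WRKY40, AT2G43590 and XTH18 were chosen after their values were seen.

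Between 3 and 5 weeks the floral repressor genes TFL1 and TEM1 and the jasmonate gene LOX2 fell in the mutant apex, and the flavonol gene FLS1 rose. TFL1 fell from 31.1 ± 1.86 to 17.2 ± 2.64 normalised CPM (mean ± SD, n = 3 each), a log2 fold change of -0.86 (SE 0.11), with an adjusted p = 2.17e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. TEM1 fell from 35.0 ± 1.86 to 11.9 ± 1.69 (SD, n = 3 each), a log2 fold change of -1.56 (SE 0.10; edgeR adjusted p = 1.74e-08). LOX2 (Aa_G49590) fell from 135 ± 42.7 to 4.84 ± 4.45 (SD, n = 3 each), a log2 fold change of -4.80 (SE 0.35; edgeR adjusted p = 7.61e-08). FLS1, the flavonol synthase gene, rose from 6.83 ± 0.942 to 24.2 ± 1.70 (SD, n = 3 each), a log2 fold change of 1.82 (SE 0.11; edgeR adjusted p = 1.69e-08). TFL1, TEM1 and LOX2 were listed higher and FLS1 lower in the mutant at the 3-week apex, so these changes are not independent of that listing.

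**Figure D3:**
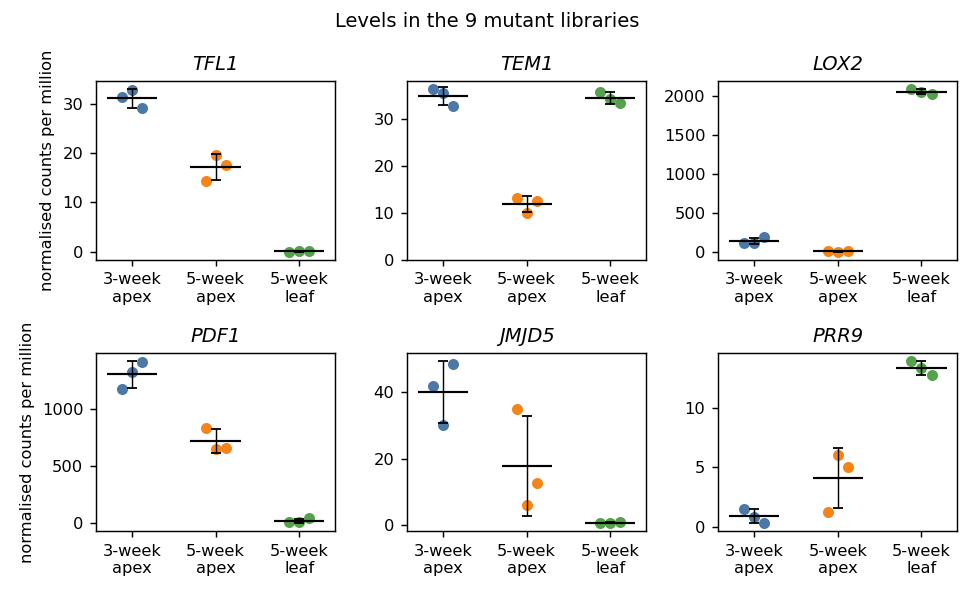
Normalised CPM of 6 genes in each of the 9 mutant libraries (points), with the group mean (line) and SD (bars, n = 3). TFL1 lies between 29.1 and 32.8 at the 3-week apex and between 14.4 and 19.6 at the 5-week apex, and PDF1 in leaf replicate 3 lies at 39.2.

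Over all genes, 8265 of the 20633 tested passed an adjusted p of 0.05 between the apex ages, 3933 higher and 4332 lower at 5 weeks (47.6% higher). That balance depended on scaling, with 66.2% of calls higher when libraries were scaled by total counts alone (5793 against 2964) and 40.1% with RLE size factors (3381 against 5049). DESeq2, which differs in its filter and test as well, gave 37.2% higher (2693 against 4542). The median log2 fold change of all genes was 0.01, and 0.12 by total counts. A change of at least 2-fold was held by 1505 of the called genes, 584 higher and 921 lower.

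The genes that rose most from 3 to 5 weeks, among those with an Arabidopsis name, included PIL1, TT7, BRG2, LNK4 and BBX28. Only genes of the authors' lists have such a name, so this ranking runs over genes chosen partly on these libraries. TT7, LNK4 and BBX28 were listed lower in the mutant at the 3-week apex, the baseline here, and LNK4 at the 5-week apex as well. PIL1, a light-regulated transcription factor gene, rose from 0.110 ± 0.135 to 1.97 ± 1.53 (SD, n = 3 each), a log2 fold change of 4.03 (SE 0.94; edgeR adjusted p = 0.00299). TT7, which encodes flavonoid 3'-hydroxylase, changed by 2.28 (SE 0.26) on the log2 scale, BRG2 by 1.91 (SE 0.10), the clock-regulated LNK4 by 1.78 (SE 0.34) and the B-box gene BBX28 by 1.65 (SE 0.35). Among the named genes that fell most were those of a catalase and a carbonic anhydrase, both abundant in the leaf. Leaf levels enter the average log2 CPM of the naming rule. CAT2, the gene of a peroxisomal catalase, had 1.03 ± 1.49 (SD, n = 3) CPM at 3 weeks and 0 counts at 5 weeks, at least 15.6-fold lower. Most of its counts came from 3-week apex replicate 1, without which the bound was 2.56-fold and the edgeR adjusted p was 0.0295. The carbonic anhydrase gene CA1 fell from 16.9 ± 14.0 to 0.549 ± 0.383 (SD, n = 3 each), a log2 fold change of -4.93 (SE 0.67). The threonine aldolase gene THA1 and GASA6, of a gibberellin-regulated family, fell with log2 fold changes of -4.92 (SE 0.24) and -4.25 (SE 0.39). Among genes that the authors' lists pair with no Arabidopsis gene, Aa_G419700 rose by 2.87 and Aa_G48790 by 2.37 on the log2 scale. In the same class, Aa_G203760 and Aa_G574220 were at least 14.5-fold and 9.47-fold lower. A bound against a group without counts used 3 counts over that group, and bounds and intervals cover counting error only. Several of these changes rested in part on 1 library: without 3-week apex replicate 1 the log2 fold change of CA1 was -4.06 and that of PIL1 5.50. Without 5-week apex replicate 3 that of LOX2 was -5.84, and without 5-week apex replicate 1 that of GASA6 was -6.20.

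All 4 measured gibberellin genes fell with age, and so did some members of the auxin, glucosinolate and jasmonate lists, but none of these 4 camera calls held with an estimated correlation. The rotation test fry, which does not set a list against other genes, did pass these lists. Its adjusted p-values were 6.68e-05 for gibberellin, 1.26e-04 for auxin, 0.0115 for glucosinolate and 0.0134 for jasmonate. Fry did not pass the salicylic acid and cytokinin lists (adjusted p = 0.234 and 0.912). The touch gene TCH4, a marker of handling, fell too, with a log2 fold change of -0.65 (SE 0.18), as did the xylem markers LAC4 and LAC17, with -0.69 and -0.80. The phloem marker SUC2, with -1.27 (SE 0.16; edgeR adjusted p = 1.35e-05), and the stomatal lineage marker TMM, with -0.89 (SE 0.21; 0.00305), fell as well and kept their calls without any single library. The calls of TCH4, LAC4 and LAC17 were each lost without some single library, as for TCH4 without 3-week apex replicate 3 (adjusted p = 0.0516), LAC4 without 5-week apex replicate 2 (0.0655) and LAC17 without 5-week apex replicate 2 (0.130). Members of each list measured here are those that the authors' lists pair with an Arabidopsis gene, chosen partly on these libraries, so the counts and directions of these lists are not independent evidence. Of the gibberellin genes, the log2 fold changes were -3.31 (SE 0.29) for GA20OX2, -1.22 (SE 0.16) for GA2OX2, which inactivates gibberellin, and -0.38 (SE 0.09) for the DELLA gene RGL3, and all 4 passed adjusted over the list alone. The set test camera gave an adjusted p = 0.0134 with a preset correlation (limma, Benjamini-Hochberg over 7 lists) and an adjusted p = 0.139 with an estimated correlation. With total counts alone, 3 of the 4 passed.

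Of 6 auxin genes, 3 fell and 1 rose, and 4 passed adjusted over the list alone. IAA29, IAA1 and IAA19 fell with log2 fold changes of -3.66 (SE 0.27), -1.62 (SE 0.16) and -0.58 (SE 0.10), while YUC6 rose by 1.22 (SE 0.31) on the log2 scale. Without 5-week apex replicate 2 the value of IAA29 was -4.42. The camera test of the list gave an adjusted p = 0.0257 with the preset and an adjusted p = 0.163 with an estimated correlation. Of 8 glucosinolate genes, 4 fell and 0 rose (6 adjusted over the list alone), among them CYP83B1, with a log2 fold change of -0.77 (SE 0.11), and the regulator gene MYB29, with -1.38 (SE 0.23). The glucosinolate list had a camera adjusted p = 0.0153 with the preset, an adjusted p = 0.258 with an estimated correlation, and an adjusted p = 0.0591 without 5-week apex replicate 1. CYP79F1 fell by 2.18 (SE 0.63; edgeR adjusted p = 0.0116), but not past the threshold without 3-week apex replicate 1 (log2 fold change -0.88, adjusted p = 0.0849) or without 5-week apex replicate 3 (log2 fold change -1.88). Of 5 jasmonate genes, 2 fell, LOX2 and AOS, the latter with a log2 fold change of -1.24 (SE 0.21), and 2 passed adjusted over the list alone. JAZ1 did not pass (log2 fold change -0.35, edgeR adjusted p = 0.128), though it did as lower without 5-week apex replicate 3 (-0.68, adjusted p = 0.00176). The jasmonate list had a camera adjusted p = 0.0257 with the preset, an adjusted p = 0.300 with an estimated correlation, and an adjusted p = 0.0686 without 5-week apex replicate 1.

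Several evening clock genes fell and the morning gene PRR9 rose between the ages, while the evening gene PRR5 did not pass (log2 fold change 0.12, edgeR adjusted p = 0.423). Of 9 clock genes, 5 fell and 1 rose (6 adjusted over the list alone), and the list as a whole did not pass camera (adjusted p = 0.135 over the 7 lists). It did pass the rotation test fry (adjusted p = 0.00246), which does not set the list against other genes. BOA, LUX and ELF4 fell with log2 fold changes of -1.38 (SE 0.18), -0.90 (SE 0.12) and -1.14 (SE 0.24), and PRR9 rose by 2.18 (SE 0.49) on the log2 scale. PRR9 levels in the 5-week apex replicates were 1.22, 6.01 and 5.02 CPM, and without 3-week apex replicate 1 its log2 fold change was 2.81. Of 7 salicylic acid and defence genes, 2 rose, WRKY46 by 1.59 (SE 0.39) and WRKY54 by 0.80 (SE 0.20), and both passed adjusted over the list alone (camera adjusted p = 0.228). PAD4 did not pass (edgeR adjusted p = 0.0534), though it did as higher with total counts alone (0.0156), without the expression filter (0.0288), with only the 2 apex groups fitted (0.0481) and without 5-week apex replicate 1 (0.0209) or 2 (0.0194). Of 3 cytokinin genes, ARR15 rose by 1.21 (SE 0.17) and CKX5 fell by 0.45 (SE 0.15). All 3 passed adjusted over the list alone, and camera gave an adjusted p = 0.980. The call of CKX5 ended without 5-week apex replicate 1 (adjusted p = 0.116) or 3 (0.0612), without 3-week apex replicate 1 (0.0638) or 2 (0.0973), with total counts alone (0.0955) and with limma-voom (0.0569). The mean and median of the cytokinin list were negative, while the rotation test fry gave it an upward direction with a p of 0.912. YUC6 and PRR9 lay outside the naming rule and were chosen after their values were seen.

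Single members of other lists changed with age as well. SEN1 fell from 53.7 ± 9.57 to 6.68 ± 3.09 (SD, n = 3 each), a log2 fold change of -3.01 (SE 0.21; edgeR adjusted p = 4.82e-08), and NYC1, which acts in chlorophyll breakdown, fell by 0.38 (SE 0.06) on the log2 scale. The gynoecium gene HEC1 fell by 2.14 (SE 0.45) on the log2 scale, with a value of -2.96 without 5-week apex replicate 1 and -1.63 without replicate 2. The cyclin gene CYCB1;3 had a log2 fold change of -0.41 (SE 0.11; edgeR adjusted p = 0.00746). The epidermal PDF1 was 1303 ± 119 at 3 weeks and 714 ± 106 (SD, n = 3 each) at 5 weeks and did not pass (edgeR adjusted p = 0.0846), though it did with limma-voom (0.00816), without the expression filter (0.0267), with only the 2 apex groups fitted (4.02e-05) and without 5-week apex replicate 1 (0.0345). The main fit shares its estimate of spread with the leaf libraries, where PDF1 was 15.6 ± 20.5 (SD, n = 3), while the apex groups did not overlap. LHCB2.1 did not pass either (edgeR adjusted p = 0.307), with a log2 fold change of 0.69 and an adjusted p = 0.000265 without 5-week apex replicate 1. SPL4 and BRC1 did not pass (edgeR adjusted p = 0.144 and 0.621), and FT had 0 counts in every apex library.

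The leaf differed from the 5-week apex at most genes, with carbonic anhydrase and catalase transcripts far higher and TFL1 almost absent. CA1 rose from 0.549 ± 0.383 CPM in the apex to 8681 ± 244 in the leaf (SD, n = 3 each), a log2 fold change of 13.93 (SE 0.60; edgeR adjusted p = 1.66e-12). LOX2 stood at 2057 ± 30.8 (SD, n = 3) in the leaf, a log2 fold change of 8.73 (SE 0.38; edgeR adjusted p = 2.31e-12). TFL1 had 782 counts over the apex libraries and 2 over the leaf libraries, a ratio of 235 with a 95% counting interval from 64.8 to 1944. FT had 0 counts in the apex and 103 in the leaf, with a leaf level of 3.74 ± 1.07 (SD, n = 3), at least 56.9-fold higher. TEM1 was higher in the leaf, at 34.5 ± 1.21 (SD, n = 3), by 1.54 (SE 0.10; edgeR adjusted p = 5.25e-10) on the log2 scale.

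Over all genes, 16316 of 20633 passed an adjusted p of 0.05 in edgeR, 7659 higher and 8657 lower in the leaf (46.9% higher), and 9094 of them changed by at least 2-fold. With total counts alone, 22.0% of the calls were higher (4026 against 14239), and the median log2 fold change of all genes moved from -0.10 to -0.93. Directions below are therefore relative to the TMM-scaled level.

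CAT2 had 0 counts in the 5-week apex and 674 ± 42.5 (SD, n = 3) CPM in the leaf, at least 10265-fold higher. The gibberellin-regulated gene GASA1 was at least 4590-fold higher, the expansin gene EXPA16 at least 357-fold and the auxin synthesis gene YUC8 at least 300.2-fold. A second carbonic anhydrase gene, CA2, rose by 10.89 (SE 0.28) on the log2 scale, and the oligopeptide transporter gene OPT1 had a ratio of 1732 with a 95% counting interval from 310.2 to 68488. Aa_G431480, which the authors' lists pair with no Arabidopsis gene, was at least 1536-fold higher. Lower in the leaf were the vacuolar iron transporter gene VIT1, at least 79.4-fold, and AT5G19100, at least 131-fold. The myrosinase-binding protein gene MBP1 fell from 150 ± 23.7 to 1.39 ± 0.0629 (SD, n = 3 each), a log2 fold change of -6.75 (SE 0.17). JMJD5 fell by 4.92 (SE 0.78) on the log2 scale, with a value of -3.98 without 5-week apex replicate 1. PDF1 fell by 5.53 (SE 0.50; edgeR adjusted p = 3.18e-08), with a value of -7.58 without leaf replicate 3. Without 5-week apex replicate 3 the log2 fold changes of CA1 and LOX2 were 14.64 and 9.76. Aa_G1117920 and Aa_G594230 were at least 1199-fold and 1076-fold lower.

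Most measured members of every tested list differed between leaf and apex, but no fixed list as a whole passed camera. The rotation test fry did pass all 7 lists, the largest adjusted p being 0.00185, for salicylic acid and defence. Fry does not set a list against other genes, and 16316 of the 20633 genes passed here, so its outcome says little about these lists. The measured members, too, are genes of the authors' lists and not independent evidence. All 8 glucosinolate genes passed (8 adjusted over the list alone), 7 of them higher in the leaf, with log2 fold changes of 7.72 (SE 0.39) for BCAT4, 7.29 (SE 0.38) for CYP79F1 and 3.73 (SE 0.23) for MYB51. The camera adjusted p of that list was 0.0690 over 7 lists (unadjusted p of 0.00986), and 0.0245 without 5-week apex replicate 3. It was 0.551 with an estimated correlation. With total counts alone, 6 of the 8 were higher and 1 lower. Of 6 auxin genes, 4 were higher and 2 lower (6 adjusted over the list alone), including IAA29 and IAA19 with log2 fold changes of 7.89 (SE 0.18) and 3.95 (SE 0.09). Without 5-week apex replicate 2 the value of IAA29 was 8.65, and that of BCAT4 8.31 and of CYP79F1 7.88. Camera gave the auxin list an adjusted p = 0.266.

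All 9 clock genes passed (9 adjusted over the list alone), 3 higher and 6 lower in the leaf, with a camera adjusted p = 0.314. Under total counts alone, 2 were higher. CCA1 rose by 4.53 (SE 0.26), and TOC1 and LUX fell with log2 fold changes of -2.24 (SE 0.11) and -1.92 (SE 0.16). All 5 jasmonate genes passed (5 adjusted over the list alone), 4 of them higher, with LOX3 at 2.68 (SE 0.28) and AOS at 2.00 (SE 0.21) on the log2 scale (camera adjusted p = 0.314). Of 7 salicylic acid and defence genes, 4 were higher and 1 lower in the leaf (5 adjusted over the list alone), but with total counts alone 2 were higher and 3 lower. CBP60G rose by 4.07 (SE 0.30), SARD1 by 3.45 (SE 0.41; 4.14 without 5-week apex replicate 1), and EDS5 fell (edgeR adjusted p = 0.00114), with a camera adjusted p = 0.314 for the list. The 3 cytokinin genes all passed (3 adjusted over the list alone), CKX5 and CKX3 higher by 3.32 (SE 0.13) and 3.56 (SE 0.38), and ARR15 lower, at -1.44 (SE 0.18), on the log2 scale (camera adjusted p = 0.397). Of the 4 gibberellin genes, 2 were higher and 2 lower (4 adjusted over the list alone), GA20OX2 by 3.24 (SE 0.31) among the former (camera adjusted p = 0.725).

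Among other list members, the phloem gene SUC2 rose by 4.84 (SE 0.15), LHCB2.1 by 4.71 (SE 0.30) and SPL4 by 3.54 (SE 0.26) in the leaf on the log2 scale. The abscisic acid genes RAB18 and NCED3 rose by 7.34 (SE 0.43) and 4.07 (SE 0.25), and the lignin laccase genes LAC4 and LAC17 by 2.57 (SE 0.19) and 2.27 (SE 0.27). CYCB1;3 and TMM fell with log2 fold changes of -2.38 (SE 0.15) and -1.37 (SE 0.28), the latter -2.01 without leaf replicate 3. The flavonoid genes FLS1 and TT7 had log2 fold changes of -1.26 (SE 0.12) and -1.58 (SE 0.26). BRC1, KAT1 and HEC1 did not pass (edgeR adjusted p = 0.323, 0.422 and 0.884), although BRC1 did without leaf replicate 2, with a log2 fold change of -1.23 and an adjusted p = 0.0168. Against the 3-week apex in place of the 5-week apex HEC1 was lower in the leaf, with a log2 fold change of -2.25 and an edgeR adjusted p = 9.28e-04. With total counts alone BRC1 and KAT1 passed as lower (adjusted p = 0.00772 and 0.000940).

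Genes that the authors listed in one organ were followed in the comparison that shares no library with that list. Of the genes higher in the mutant leaf, 390 were tested between the apex ages, where 155 were lower and 76 higher at 5 weeks (camera adjusted p = 0.00110 over 2 lists). That call ended with an estimated correlation, at an adjusted p = 0.457, and 242 members passed adjusted over the list alone. For the 616 genes lower in the mutant leaf, 108 were higher and 128 lower (234 adjusted over the list alone; camera adjusted p = 0.949). Of the genes higher in the mutant 3-week apex, 238 were tested between leaf and 5-week apex, where 133 were higher and 76 lower in the leaf (209 adjusted over the list alone; camera adjusted p = 0.00446). An estimated correlation ended this call too, at an adjusted p = 0.235. Of the 75 genes lower in the mutant 3-week apex, 40 were lower and 19 higher in the leaf (59 adjusted over the list alone; camera adjusted p = 0.0556), with an adjusted p of 0.0432 without 5-week apex replicate 1, 0.0457 without leaf replicate 1 and 0.0470 without leaf replicate 2. With an estimated correlation camera gave this list an adjusted p = 0.151. The authors chose these lists by setting other libraries of this series against controls that are not samples of it.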

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

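The tests of the clock genes, of leaf replicate 3 and of leaf tissue below were chosen after the results were seen. What the regrouping of libraries was to show was also written down after them.

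The share of reads assigned to no gene differed between the groups, with means of 10.8% at the 3-week apex, 14.9% at the 5-week apex and 8.08% in the leaf. These reads were not analysed here, and the range over single libraries was 7.94% to 16.3%.

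Evening clock genes were higher and morning clock genes lower in the mutant wherever the authors listed them, with an exact permutation p of 0.0119 (two-sided). The same test over single libraries gave 0.0119 for 5-week apex replicate 1 (evening minus morning 1.45) and also for replicate 2 (-1.34), each 0.0536 when adjusted over the 9 libraries, and 0.0238 and 0.0476 for 3-week apex replicates 1 and 2. In 5-week apex replicates 1, 2 and 3 JMJD5 stood at 34.9, 6.07 and 12.5 CPM, COR27 at 3.48, 0.334 and 1.92, and PRR9 at 1.22, 6.01 and 5.02. A harvest at different times of day could give both patterns, and no harvest time is known, so the tables cannot tell this from a change of the clock itself. Whether the mutation alters the clock stays open and untested.

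PDF1 and some other genes higher in the mutant leaf owed their means largely to leaf replicate 3, where 7 of 391 such genes (ASN1, PDF1, AT4G29020, KCS19, AT3G56220, GPAT6 and Aa_G342840, chosen after their values were seen) were at least 3 times the other replicates, against 0 in replicates 1 and 2. Other libraries also carried such genes, 6 of 62 in 5-week apex replicate 3, 2 of 62 in 5-week apex replicate 1 and 7 of 238 in 3-week apex replicate 1, so leaf replicate 3 is not alone. It was also the lowest of the 3 leaf libraries for 450 of 618 genes listed lower in the leaf that had counts in each. In a like way, 5-week apex replicate 1 was the lowest for 24 of 40 genes listed lower at that age. The 5-week apex replicate 2 was the lowest for 44 of 61 genes listed higher, where a low library lessens the fold. The median of replicate 2 for these genes was 0.699 of the mean of the other replicates. Tissue like the 5-week apex in leaf replicate 3 could raise epidermal genes, but the median share of apex tissue that the 7 genes would need was 35.4%. Abundant apex genes allow far less, the tenth-lowest of 1696 giving 0.372%, and 30 of them allow less than the 4.96% that PDF1 needs. A biological difference of that sample, such as leaf age or stress, stays open and untested.

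Several named genes that fell most between the apex ages were abundant in the leaf. The naming rule averages log2 CPM over all 9 libraries, so a gene as low in the apex as CAT2 could enter only through leaf counts. Leaf abundance of these genes is therefore partly set by the rule. Tissue like the 5-week leaf in the 3-week apex samples could explain their fall. Of the 10 lowest named genes, 8 would need at least 1.12% of leaf, more than 2 times the 0.385% that the tenth-lowest of 2296 abundant leaf genes allows. The other 2 genes, CAT2 and CA1, need no more than 2 times the allowed share, so leaf tissue stays open for these 2. A first form of this test, over 67 genes and with a bound of 5.10%, put 7 of the 10 above its bound. Younger leaf tissue than that of 5 weeks was not tested and stays open.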

How the results depend on the processing

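Most alternative settings were chosen before the data were seen, and leave-one-out runs of the list tests and RLE scaling of the authors' lists were chosen after. Where a result changed, the cause was not tested.

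Of 8265 genes between the apex ages, 5418 passed at an adjusted p under 0.01 and 1505 with a change of at least 2-fold, and other settings and tools gave 7235 to 8757. With 1 library left out the count lay between 6256 (without 3-week apex replicate 3) and 8513 (without 5-week apex replicate 1). Of 16316 genes between leaf and apex, 9094 changed by at least 2-fold, 14817 passed under 0.01, and leave-one-out counts lay between 15689 and 16323. Replicate number as a block gave 7681 and 16114.

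The 4 fixed lists that camera called between the ages became 0 with an estimated correlation, and leave-one-out counts lay between 2 (without 5-week apex replicate 1) and 4. For leaf against apex camera called 0 lists, and 0 to 1 with a library left out. The 1 authors' list called between the ages became 0 with an estimated correlation and stayed 1 with any library left out. Between leaf and apex 1 list was called, 0 with an estimated correlation, 2 with RLE scaling (adjusted p = 0.0376) and 1 to 2 with a library left out. The overlap of genes higher at the 5-week apex and lower in the leaf was 3 genes, with an adjusted p = 0.277, at the authors' adjusted p under 0.01.

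With the 3-week apex in place of the 5-week apex, 5 genes took the other sign in the leaf: SEN1 -1.62 (adjusted p = 1.34e-06), FLS1 0.57 (0.00114), TT7 0.70 (0.0593), TEM1 -0.0179 (0.869) and GA20OX2 -0.0703 (0.784). These 5 follow from their own changes between the apex ages. ARR15 no longer passed there (-0.23, adjusted p = 0.304).

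Between the ages 52 named genes passed, and 5 of them lost the call without 1 library. These were CKX5, CYP79F1, TCH4 (adjusted p = 0.0516 without 3-week apex replicate 3), LAC4 (0.0655 and 0.0527 without 5-week apex replicates 2 and 3) and LAC17. LAC17 lost it without any of 5 libraries (0.0507 to 0.130), with total counts alone (0.0501) and in DESeq2 (0.119). Between leaf and apex 0 of 62 were lost. Gained between the ages were RAB18 without the expression filter (0.0467), in DESeq2 (0.00313) and with replicate number as a block (0.00276), KAT1 without 3-week apex replicate 2 (0.0371) and JAZ1 without 5-week apex replicate 3 (0.00176).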

Other observations

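The counts of genes with opposite directions and the regrouping of libraries were read after the results were seen, and what the regrouping was to show was written down after them.

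By the authors' deposited table, 17 genes had opposite directions in an apex and in the leaf, and 0 between the apex ages. They include CYP79B2, CYP79B3, AOC2, WRKY40, XTH18, BBX28 and CML41, with CYP79B3 at a fold of 8.09 at the 5-week apex and at 0.361 in the leaf. Its 5-week apex level rests on replicate 3 (2.51 CPM, against 0.322 and 0.334 in replicates 1 and 2). Those outside the naming rule were chosen after their values were seen. Whether such changes differ between settings was not tested, as the control libraries were not analysed here.

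Libraries of 2 groups can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The share of splits reaching the real count was 1 of 10 for both contrasts, with 8265 calls between the ages and 16316 between leaf and apex, and at most 0 calls in any other split.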
